A study of Homo sapiens with 6 samples.

How the data were processed

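Gene expression was measured by RNA sequencing in MCF-7 cells, an established estrogen-receptor-positive breast cancer cell line, kept for 24 h in control medium or in medium with 5 µM DpC. DpC is a thiosemicarbazone that binds iron and copper. Each group held 3 libraries, named here Control replicates 1 to 3 and DpC replicates 1 to 3 after the sample titles. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

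Per the series' design text, the authors trimmed the reads with Trim Galore 0.4.4, aligned them with STAR 2.5 to the human genome, tagged duplicates with Picard 1.138 and computed expression in R 3.4.3 with Rsubread 1.28.0, limma 3.34.1 and edgeR 3.20.1. The genome build is hg38 per the design text and the labels' protocols, whereas a sample description names hg19. The annotation behind the gene rows, and whether counting used the strand of the reads, are not given in the sources used here. Although the deposited table is named for RPKM, it holds read counts: its values are whole numbers, single reads are present, and the column totals differ between libraries. The deposited counts were therefore used as raw counts per gene, with 28395 genes under NCBI gene numbers and 1 column per library. Every column belonged to a sample of the series, and no row lacked a gene number. All 37 mitochondrial genes in the table were listed at 0 in every library, so nothing is said of their expression.

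Gene symbols were taken from the NCBI RefSeq table of assembly GRCh38.p14, which matched 27745 of the gene numbers and left 650 unmatched. The unmatched rows held 0.0441% to 0.0549% of the reads of a library. Coordinates are those of GRCh38.p14 and cover the annotated gene from its first to its last base. The counts themselves carry no coordinates.

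The design chosen before the data were examined foresaw limma on log2(RPKM + 0.5) if the table held RPKM and edgeR's quasi-likelihood test if it held counts, so the count test was used. Genes with a mean of at least 0.5 CPM (counts scaled to a library total of 1e6) over the 6 libraries were tested, the CPM minimum standing in for the same minimum in RPKM. This left 14516 genes tested and 13879 not tested. Libraries were scaled with TMM, the dispersion was estimated, and glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3 compared DpC with control, without a replicate term. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05, and a second count also required a change of at least 2-fold. Standard errors of log2 fold changes were computed as the size of the fold change over the square root of the F statistic. Levels are TMM-normalised CPM, given as mean ± SD over 3 libraries.

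Before the data were examined, 30 gene lists with 651 distinct genes were written from textbook knowledge, among them markers of fibroblasts, leukocytes, endothelium and basal epithelium. For each list the members called higher, called lower and not called were counted, over all genes and adjusted over the list alone. The 28 lists with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over these lists, and again with a correlation estimated per list. The genes named by rule were the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM in the higher group and no overlap between the groups, 12 genes fixed by name, and, for each list past the camera threshold, the 2 called members with the largest change (3 where more than 10 members were called). Other genes named were chosen after their values were seen: list members outside this rule, PGK2, the metallothionein genes next to those named, and the genes and families that open the other observations.

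Library totals ranged from 29734579 to 41974134 reads. Where all libraries of a group held 0 reads, the fold is a lower bound against a floor of 3 reads over that group. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Chi-square comparisons of the counts within each group, over genes with at least 20 reads in the pair, gave 2.32 to 26.4 per degree of freedom, so no pair matched within sampling noise. Simulated counts for 14193 genes, with 200 changed and a further list raised, were drawn from the means of the control libraries and the totals of all libraries. The fit was tested on them for the comparison of DpC with control. It recovered 74.6% of genes changed 1.5-fold, 97% of those changed 2-fold and 100% of those changed 4-fold, with 8 false calls (3.81% of the calls). A raised list was found, and 0 of 100 unchanged lists had a camera p under 0.05. The simulated genes were independent and most were unchanged, whereas 78.7% of the genes tested were called in the data. These rates may therefore not hold for the data.

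The alternatives chosen beforehand that applied to counts were no filter, median-of-ratios scaling, quantile normalisation, a replicate block, an estimated list correlation and leaving out each library in turn. The pseudocounts, stricter filter and TPM rescaling chosen beforehand were written for RPKM and could not be run as written. In their place a filter at 2 CPM, limma on log2(CPM + 0.5), log2(CPM + 0.1) and log2(CPM + 1), limma without a trend or with a robust fit, edgeR with a robust fit, DESeq2 1.42.0 and scaling by library totals alone were added after seeing the data. For the deviation of gene lists in Control replicate 1, each member was matched to genes within 1 percentage point of GC content and 0.5 of log2 CPM. Sequences and neighbours of the metallothioneins, GC content, and the host genes and exons of small RNAs came from a GENCODE annotation of GRCh38. Gene classes, and which lncRNA genes overlap another gene, came from the RefSeq table. The figures were drawn with matplotlib 3.10.9.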

Results

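RNA was sequenced from MCF-7 cells, an estrogen-receptor-positive breast cancer line, after 24 h in control medium or in medium with 5 µM DpC, a thiosemicarbazone that binds iron and copper. The series addresses DpC and a related compound, Dp44mT, as agents against estrogen-receptor-positive breast cancer. The samples held DpC alone, so the comparison asks which transcripts changed under DpC. Each group held 3 libraries. The control libraries held 41974134, 31393343 and 37404542 counted reads and the DpC libraries 31544605, 31730354 and 29734579, over 19458 to 20268 genes with at least 1 read per library.

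After DpC, each of 30 tested targets of the hypoxia-inducible factor (HIF) rose, as did 21 of 25 p53 targets and each of 19 chaperone and unfolded protein response genes of the endoplasmic reticulum. These lists were called by camera, a gene set test, and kept the call with an estimated correlation. Of 18 glycolysis genes 16 rose, while 20 of 29 estrogen-induced genes and 29 of 39 DNA replication genes fell, and camera called these lists but lost the calls, at adjusted p = 0.0597, 0.0602 and 0.0942 with an estimated correlation. NDRG1 (gene 10397, chromosome 8, 133237175 to 133297252), a metastasis suppressor induced by iron depletion, rose from 23.4 ± 3.08 to 1842 ± 3.63 normalised CPM (SD, n = 3), a log2 fold change of 6.30 ± 0.094 (SE). ESR1 (gene 2099, chromosome 6, 151656672 to 152129619), which encodes estrogen receptor alpha, fell from 438.7 ± 6.17 to 58.7 ± 1.51 CPM, a log2 fold change of -2.90 ± 0.038. Of 14516 genes tested, 11417 (78.7%) passed edgeR's quasi-likelihood test, with 5353 higher and 6064 lower after DpC, and 3099 were not called. At least 2-fold changes were called for 1958 higher and 2087 lower genes. The groups did not overlap for 11832 genes (81.5%), against 10% by chance.

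The balance of rises and falls depended on the scaling. The 10 most abundant genes took 4.15% to 4.26% of the reads in control libraries and 6.34% to 6.37% in DpC libraries, and GAPDH was the most abundant gene in each DpC library. With TMM scaling 46.9% of the called genes were higher. With scaling by library totals alone 3813 genes were higher and 7837 lower, 32.7% higher, and the log2 fold changes moved by a median of -0.25. At least 2-fold changes then numbered 1410 higher and 3000 lower. With median-of-ratios scaling slightly more genes were higher than lower, 5728 against 5644 (50.4% higher), and at least 2-fold changes numbered 2118 higher and 1925 lower. DESeq2 called 5443 genes higher and 5264 lower. The changes below are relative to TMM scaling, under which the median log2 fold change of all genes was -0.059. Correlations of log2 values were 0.994 to 0.998 between libraries of a group and 0.912 to 0.925 between groups, and the first principal component, with 94.8% of the variance, separated the groups. Control replicate 1 stood apart from the other controls on the second component (3.11% of the variance), at 19.8 against -8.23 and -12.7.

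The largest rises included metallothioneins, small cysteine-rich proteins that bind zinc and copper. MT1B (chromosome 16, 56651886 to 56653204) had 0 reads in the controls and 9037 in the DpC libraries, at least 4280-fold higher. MT4 went from 0 to 831 reads, at least 394-fold higher, and the pseudogene MT1DP from 0 to 436 reads, at least 206-fold higher. MT1F (chromosome 16, 56657959 to 56659303) rose from 1.45 ± 0.159 to 2248 ± 73.2 CPM, a log2 fold change of 10.60 ± 0.077, and MT1X from 4.37 ± 0.735 to 1467 ± 44.6 CPM, a log2 fold change of 8.41 ± 0.10. Metallothionein genes are close paralogs, so reads of one can be counted for another. NPPB, which encodes the natriuretic peptide BNP, went from 0 to 4082 reads, at least 1930-fold higher. SLC30A2, a zinc transporter, went from 0 to 95 reads, at least 45-fold higher. CA9, a carbonic anhydrase induced by hypoxia, rose from 0.038 ± 0.034 to 31.2 ± 1.38 CPM. These 8 genes had the largest rises by the rule set beforehand, and each was called by edgeR with an adjusted p of at most 6.44e-05. The ranking used edgeR's fitted log2 fold changes, which are loosely set where a group held 0 reads. For SLC30A2 the fitted value was 8.26, against 1.67 with limma on log2(CPM + 0.5), so its rank is uncertain.

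**Figure D1:**
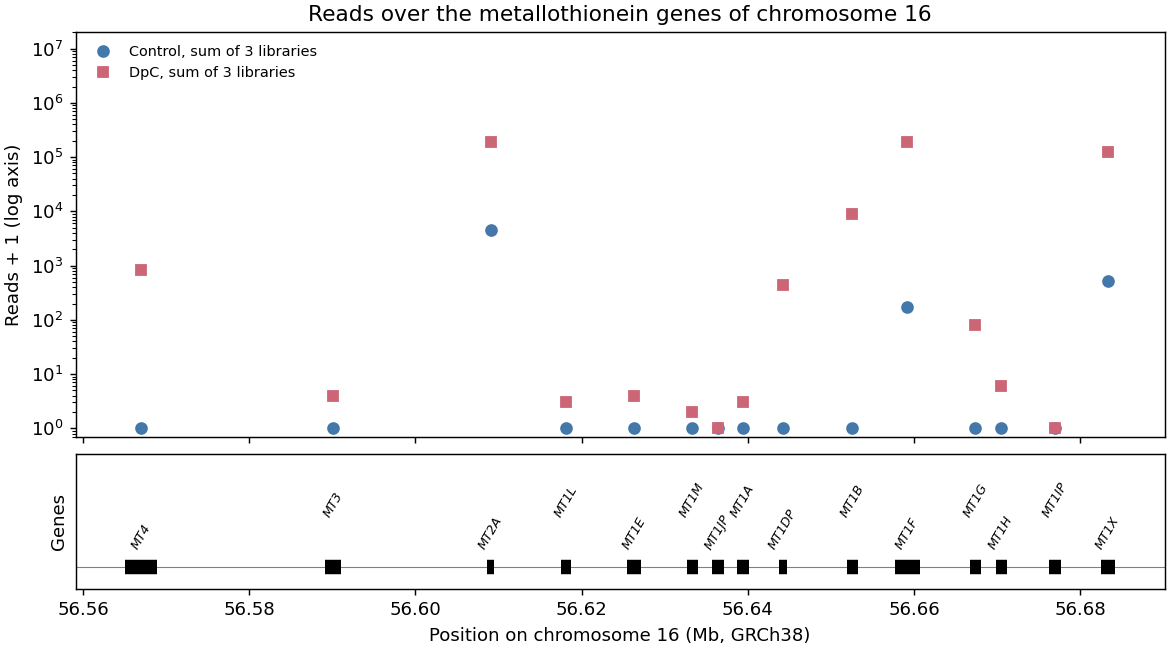
Reads over the metallothionein genes of chromosome 16, as reads plus 1 on a log axis against position in Mb on GRCh38, summed over the 3 control libraries (circles) and the 3 DpC libraries (squares) without scaling for depth; black boxes below mark the genes. MT1F held 175 reads in controls and 191459 after DpC, MT1B 0 and 9037, while MT1A held 0 and 2.

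The 8 largest falls were gene 105373474, which matched no symbol, CCDC87, AMER2, ELOVL2-AS1, MIR503HG, LINC01522, KCNJ8 and RIMBP3. Gene 105373474 went from 170 reads in the controls to 0, at least 39.9-fold lower. AMER2, a regulator of Wnt signalling, fell from 5.87 ± 0.108 to 0.213 ± 0.070 CPM, a log2 fold change of -4.77 ± 0.17, and the long non-coding RNA LINC01522 from 26.7 ± 1.19 to 1.14 ± 0.240 CPM, a log2 fold change of -4.54 ± 0.12. KCNJ8, a potassium channel gene, fell by 4.40 and ELOVL2-AS1 by 4.76 on the log2 scale. ELOVL2-AS1 overlaps ELOVL2, which fell by 4.25, and counting by strand is not stated, so its reads may belong to either gene. Few reads remained after DpC, and single libraries moved 3 of these values. The log2 fold change of CCDC87 was -4.94, or -5.86 without DpC replicate 2, that of RIMBP3 -4.40, or -5.71 without DpC replicate 2, and that of MIR503HG -4.68, or -5.44 without DpC replicate 1 and -4.09 without DpC replicate 2.

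Genes of iron handling moved both ways. The ferritin heavy chain FTH1, which stores iron, rose from 1130 ± 52.95 to 5090 ± 149 CPM, a log2 fold change of 2.17 ± 0.050, and the transferrin receptor TFRC, which takes up iron, from 428.4 ± 27.1 to 1036 ± 27.1 CPM, a log2 fold change of 1.27 ± 0.052. HMOX1, the heme-degrading oxygenase, rose by 6.22 ± 0.15 and TFR2 by 2.77 ± 0.23 on the log2 scale. TFR2 had few reads, from 0.169 to 1.15 CPM, and rose by 1.30 with limma on log2(CPM + 0.5). Of the 19 members tested of the list of iron uptake, storage and export genes, 11 were higher, 7 lower and 1 not called, with a median log2 fold change of 0.35. Camera gave the list an adjusted p of 0.0072, and an adjusted p of 0.0848 with an estimated correlation. The call was also lost with limma in place of edgeR, at an adjusted p of 0.102 on log2(CPM + 0.5).

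The 30 HIF targets, all higher, had a median log2 fold change of 3.92 (camera adjusted p = 3.86e-112, and 0.00451 with an estimated correlation). ANKRD37 rose by 6.88 ± 0.12, ADM, which encodes adrenomedullin, by 6.36 ± 0.096 and CA9 by 9.44 ± 0.21 on the log2 scale. VEGFA, the vascular endothelial growth factor, rose from 53.4 ± 4.07 to 820.5 ± 16.8 CPM, a log2 fold change of 3.94 ± 0.061. Of 18 glycolysis genes tested 16 rose, PFKM fell and SLC16A3, at -0.23, was not called. The median was 2.50 (camera adjusted p = 3.86e-35), with an adjusted p of 0.0597 with an estimated correlation. The aldolase ALDOC rose by 5.62 ± 0.055, the enolase ENO2 by 4.56 ± 0.037 and hexokinase HK2 by 4.33 ± 0.038 on the log2 scale. Some glycolysis genes, HK2 and ALDOC among them, were also on the list of HIF targets.

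The estrogen-induced genes fell on balance, with 7 higher, 20 lower and 2 not called among 29 tested and a median log2 fold change of -0.90. Camera gave an adjusted p of 1.09e-07, and an adjusted p of 0.0602 with an estimated correlation. EGR3 fell from 111.9 ± 2.40 to 7.75 ± 0.606 CPM, a log2 fold change of -3.85 ± 0.063, the survival gene BCL2 by 3.30 and the chemokine CXCL12 by 3.15 on the log2 scale. The progesterone receptor PGR fell from 93.5 ± 1.34 to 18.1 ± 1.28 CPM, a log2 fold change of -2.37 ± 0.059. GREB1 fell by 0.95 ± 0.049 and cyclin D1, CCND1, by 0.89 ± 0.043 on the log2 scale. The estrogen-induced genes TFF1 and TFF3 rose, by 0.58 and 1.04. Of 19 luminal epithelial genes 5 were higher, 13 lower and 1 not called, with a median of -0.57 (camera adjusted p = 0.0362), and an adjusted p of 0.218 with an estimated correlation. The androgen receptor AR fell by 2.26 and the luminal factor GATA3 by 0.93, whereas MUC1 rose by 2.43 ± 0.058 and ELF3 by 2.33 ± 0.055 on the log2 scale. This list did not pass under 11 of 18 alternatives besides the estimated correlation, among them leaving out Control replicate 2 (adjusted p = 0.0829), Control replicate 3 (0.0699) or DpC replicate 3 (0.0521). Of 19 growth factor receptors and adaptors 6 were higher, 10 lower and 3 not called. Their median was -0.31 but their mean 0.081, and camera, which gave the direction of the mean, did not call the list (adjusted p = 0.668). ERBB3 fell by 0.94 and ERBB4 by 1.07, while EGFR rose by 1.56 and its inhibitor ERRFI1 by 2.97 on the log2 scale.

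**Figure D2:**
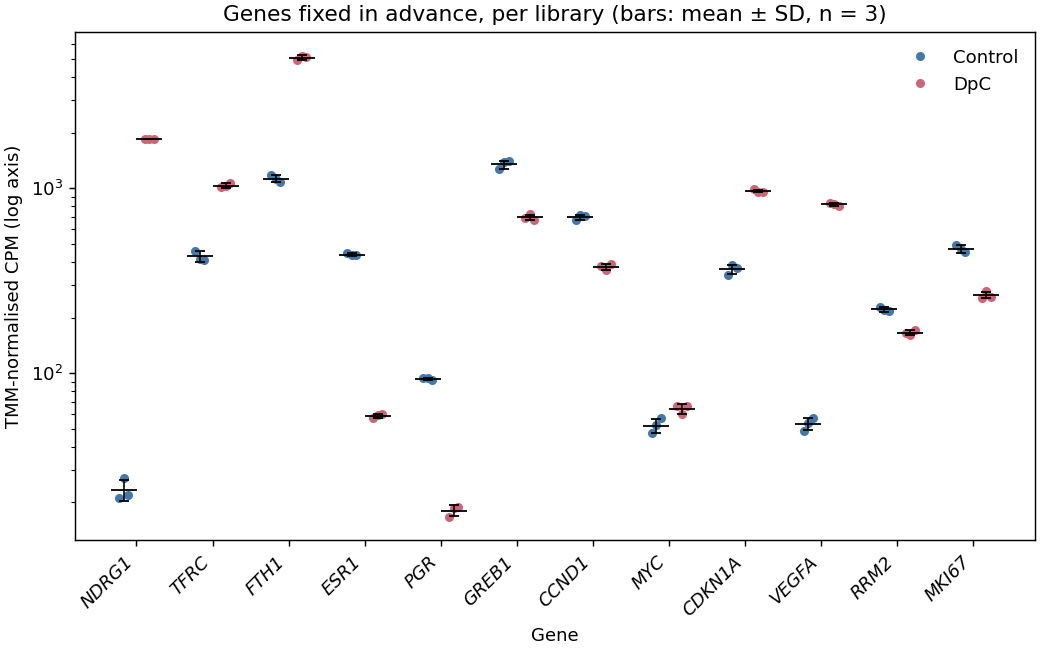
TMM-normalised CPM on a log axis for the 12 genes fixed by name, with 1 point per library, control in blue and DpC in red, and bars for the mean ± SD of 3 libraries. ESR1 lay at 438.7 CPM in controls and 58.7 after DpC, NDRG1 at 23.4 and 1842, and MYC at 52.2 and 64.3.

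Of 39 DNA replication genes 5 were higher, 29 lower and 5 not called, with a median of -0.46 (camera adjusted p = 8e-04), and an adjusted p of 0.0942 with an estimated correlation. POLE2 fell by 1.79 ± 0.086, CLSPN by 1.56 ± 0.062 and GINS4 by 1.52 ± 0.078 on the log2 scale, while the licensing factor CDT1 rose by 1.49. The ribonucleotide reductase subunit RRM2 fell from 221.4 ± 6.50 to 165.6 ± 5.01 CPM, a log2 fold change of -0.42 ± 0.040. Of 30 mitosis genes 26 fell and 4 were not called, with a median of -0.50 (camera adjusted p = 0.000452), and an adjusted p of 0.511 with an estimated correlation. Topoisomerase TOP2A fell by 1.82 ± 0.060, ASPM by 1.71 ± 0.067, BUB1B by 1.19 ± 0.056 and the proliferation marker MKI67 by 0.83 ± 0.048 on the log2 scale. Control replicate 1 lay above the mean of the other controls for 27 of the 30, by a median of 0.13, and without it 3 mitosis genes were higher and 24 lower. Of 20 genes of homologous recombination and Fanconi anaemia repair 2 were higher and 18 lower, with a median of -0.65 (camera adjusted p = 0.000909), and an adjusted p of 0.228 with an estimated correlation. BRCA1 fell by 1.53 ± 0.072, XRCC2 by 1.33 ± 0.086 and FANCD2 by 1.31 ± 0.054 on the log2 scale. Among 18 replication-dependent histone genes 2 were higher, 9 lower and 7 not called, and camera did not call the list (median -0.34, adjusted p = 0.375). Control replicate 1 lay below the other controls for 16 of these histone genes. Of 26 ribosome biogenesis genes 5 were higher, 18 lower and 3 not called, with a median of -0.63 (camera adjusted p = 0.000864), and an adjusted p of 0.0957 with an estimated correlation. UTP20 fell by 1.55 ± 0.058, and POLR1A and POLR1B, subunits of RNA polymerase I, by 1.51 ± 0.048 and 1.47 ± 0.064 on the log2 scale. MYC, a driver of growth, rose by 0.30 ± 0.075 (edgeR adjusted p = 0.0055), a call lost with scaling by library totals, where its log2 fold change was 0.05 (adjusted p = 0.535).

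Of 25 p53 targets 21 were higher, 2 lower and 2 not called, with a median of 1.28 (camera adjusted p = 4.78e-13, and 0.0156 with an estimated correlation). GDF15 rose by 3.90 ± 0.12, the pro-apoptotic BBC3 by 3.51 ± 0.13 and PLK3 by 2.98 ± 0.087 on the log2 scale. The cell-cycle inhibitor CDKN1A rose from 364.6 ± 22.6 to 968.7 ± 15.2 CPM, a log2 fold change of 1.41 ± 0.050. Of 27 targets of the integrated stress response 26 rose and PSPH fell, with a median of 1.74 (camera adjusted p = 3.33e-26), and an adjusted p of 0.0602 with an estimated correlation. ATF3 rose from 1.49 ± 0.169 to 260.0 ± 8.61 CPM, a log2 fold change of 7.43 ± 0.071, PPP1R15A by 4.22 ± 0.053 and DDIT3, which encodes CHOP, by 3.72 ± 0.073. Each of 19 chaperone and unfolded protein response genes of the endoplasmic reticulum rose, with a median of 1.20 (camera adjusted p = 5.76e-21, and 0.0156 with an estimated correlation). DNAJB9 rose by 4.50 ± 0.051, HERPUD1 by 2.74 ± 0.043 and the chaperone HSPA5 by 2.63 ± 0.046 on the log2 scale. Of 17 heat shock genes 12 were higher, 1 lower and 4 not called, with a median of 0.30 (camera adjusted p = 0.0407), and an adjusted p of 0.499 with an estimated correlation. HSPA6 rose by 3.02 ± 0.15, HSPB1 by 1.71 ± 0.29 and HSPD1 by 1.31 ± 0.088, while HSPA1A, at -0.08, was not called. Scaling by library totals ended the list's call (median 0.047, adjusted p = 0.0663).

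In the list of metallothioneins and copper or zinc transport 7 members were higher, 4 lower and 2 not called among 13 tested, with a median of 0.35 and a mean of 2.12. Camera gave an adjusted p of 6.47e-07, and an adjusted p of 0.0602 with an estimated correlation, and limma on log2(CPM + 0.5) ended the call (adjusted p = 0.148). The median ranged from 0.0959 to 1.3 over the 18 alternatives besides the estimated correlation. MT2A rose from 37.9 ± 10.8 to 2205 ± 172 CPM, a log2 fold change of 5.87 ± 0.22, and the zinc exporter SLC30A1 rose by 5.44. The zinc importer SLC39A6 fell by 2.13 and the copper transporter SLC31A2 by 0.85, while ATP7A, at -0.01, was not called. MT1G, at 0 reads in controls and 80 after DpC, lay under the minimum for testing. Of 22 NRF2 antioxidant targets 17 were higher, 2 lower and 3 not called, with a median of 1.05 (camera adjusted p = 1.46e-05), and an adjusted p of 0.228 with an estimated correlation. The cystine transporter SLC7A11 rose by 2.42 ± 0.099 on the log2 scale, and OSGIN1 from 11.9 ± 4.36 to 47.4 ± 4.30 CPM, whereas AKR1B10 fell by 1.55. The nuclear-encoded respiratory chain list was not called (6 higher, 21 lower, 10 not called of 37, median -0.16, camera adjusted p = 0.182), though quantile normalisation gave an adjusted p of 0.0163. The iron-sulfur cluster assembly list was not called either (8 higher, 13 lower, 4 not called of 25, median -0.29, adjusted p = 0.668), and NFS1, its cysteine desulfurase, fell by 0.89 on the log2 scale.

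Of 23 cholesterol synthesis genes 19 were higher, 3 lower and 1 not called, with a median of 1.32 (camera adjusted p = 3.74e-10), and an adjusted p of 0.0705 with an estimated correlation. MVD rose by 2.84 ± 0.21, MSMO1 by 2.43 ± 0.054 and STARD4 by 2.29 ± 0.059 on the log2 scale. Of 27 autophagy and lysosome genes 18 were higher, 1 lower and 8 not called, with a median of 0.36 (camera adjusted p = 0.000892), and an adjusted p of 0.0848 with an estimated correlation. GABARAPL1 rose by 2.42 ± 0.087, and the autophagy receptors OPTN and SQSTM1 by 2.24 ± 0.044 and 1.93 ± 0.079. Of 15 BCL2 family genes 11 were higher, 1 lower and 3 not called, with a median of 0.85 (camera adjusted p = 0.0107), and an adjusted p of 0.287 with an estimated correlation. The pro-apoptotic members BBC3 and HRK rose by 3.51 and 2.07, MCL1, which opposes apoptosis, rose by 0.90, and BCL2 was the member that fell. Of 23 immediate early and MAPK feedback genes 19 were higher, 2 lower and 2 not called, with a median of 1.54 (camera adjusted p = 9.43e-13), and an adjusted p of 0.0642 with an estimated correlation. The AP-1 subunits FOSB and FOSL1 rose by 3.80 ± 0.14 and 3.73 ± 0.089 and KLF6 by 3.42 ± 0.040, while DUSP6 fell by 1.14 on the log2 scale. Of 22 interferon-stimulated genes 17 rose and 5 were not called, with a median of 1.47 (camera adjusted p = 0.0142), and an adjusted p of 0.566 with an estimated correlation. IFIH1 rose by 2.70 ± 0.14, IRF1 by 2.65 ± 0.067 and IRF7 by 2.21 ± 0.26 on the log2 scale, while STAT1, at -0.20, was not called. Control replicate 1 lay above the mean of the other controls for 16 of the 22 genes, with a median of 0.23 on the log2 scale, OAS1 by 0.47 and IFIH1 by 0.34 among them, while IRF7 and ISG15 lay 1.02 and 0.77 below it. Without this library IRF7 rose by 1.93. Control replicate 2 lay below replicate 3 for 20, with a median of -0.23. With Control replicate 1 left out, 17 interferon-stimulated genes were higher, 1 lower and 4 not called, with a median of 1.60 (camera adjusted p = 0.0068).

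Of 14 genes of epithelial-mesenchymal transition 9 were higher, 2 lower and 3 not called, with a median of 0.91 (camera adjusted p = 2.48e-05), and an adjusted p of 0.0602 with an estimated correlation. Over the 18 alternatives besides the estimated correlation the list's median ranged from 0.331 to 2.23. LOXL2 rose by 5.54 ± 0.097, the integrin ITGA5 by 3.77 ± 0.081 and SERPINE1 by 3.17 ± 0.16, whereas VIM fell by 0.25 on the log2 scale. Of 10 basal epithelial markers 8 were higher and 2 lower, and camera did not call the list (median 0.44, adjusted p = 0.108). The keratins KRT5 and KRT17 rose by 4.53 and 2.93, and TP63 fell by 4.16. Markers of other cell types gave no called list. Of 5 fibroblast markers tested 3 were lower and 2 not called (median -0.80, adjusted p = 0.442), and of 5 endothelial markers 3 were higher and 2 lower (median 0.66, adjusted p = 0.855). Of 12 leukocyte markers 10 were below the minimum, the pan-leukocyte marker PTPRC with 5 control and 10 DpC reads, and the tested CSF1R and CD68 rose by 4.28 and 2.92. Counts adjusted over the list alone equalled those above except for 11 lower growth factor receptors and adaptors, 20 lower respiratory chain genes, 2 lower interferon-stimulated genes and 19 lower ribosome biogenesis genes. Camera called 21 of 28 lists, and 3 of them, the HIF targets, the p53 targets and the endoplasmic reticulum chaperones, kept the call with an estimated correlation.

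**Figure D3:**
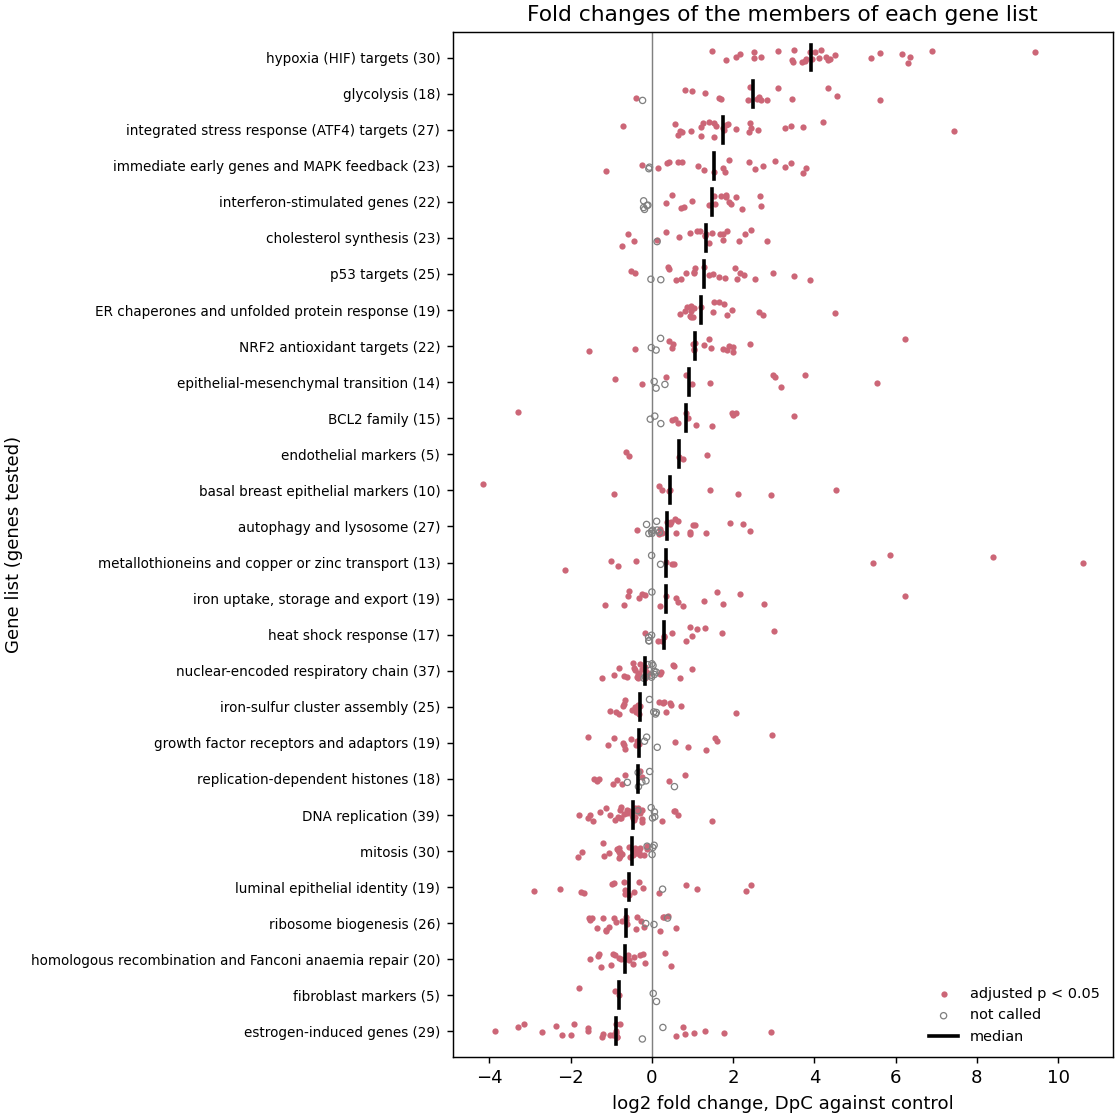
Log2 fold change of DpC against control for each tested member of the 28 lists with at least 5 tested members, filled where the edgeR adjusted p was under 0.05 and open where it was not, with a black bar at each list's median; vertical scatter within a list is random. Medians ran from -0.90 for estrogen-induced genes to 3.92 for HIF targets.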

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

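The alternative scalings by library totals, the filter at 2 CPM, the limma fits without quantile normalisation, the robust edgeR fit and DESeq2 were chosen after seeing the data, and the others beforehand. The number of genes called was 11417 and ranged from 9930 (filter at 2 CPM, 12301 genes tested) to 12773 (no filter, 22647 genes tested) over the alternatives with all libraries, and DESeq2 called 10707. At least 2-fold changes numbered 4045, from 2902 with limma on log2(CPM + 1) to 5410 without a filter, and DESeq2 gave 4032. Leaving out 1 library gave 10670 to 11958 genes and 3868 to 4117 at least 2-fold changes. Without Control replicate 1, 11958 genes were called, 11039 of them shared with the full set. Deviations of same-numbered libraries correlated at -0.27, 0.081 and -0.32, and other pairs reached 0.36, so the replicate numbers gave no sign of pairing. With 3 libraries per group and Control replicate 1 standing apart, these values cannot exclude a pairing. With the number as a replicate block 10893 genes were called, 4056 of them at least 2-fold, and the luminal list lost its call (adjusted p = 0.0638).

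Of 1072 values of the 83 named genes under the alternatives with all libraries, 1071 kept their direction and call, and the exception was MYC with library totals. All 495 values with 1 library left out kept both. Apart from the 12 genes fixed by name, MYC among them, these genes were picked because they were called with large changes in the same data. Most of these values were therefore likely to keep their call. Limma and quantile normalisation gave smaller fold changes for genes with few reads in a group, since the pseudocount bounds them. CA9 had a log2 fold change of 9.44 with edgeR, 5.88 with limma on log2(CPM + 0.5) and 5.79 with quantile normalisation. FTH1, which had many reads in both groups, also moved with quantile normalisation, from 2.17 to 1.53. The pseudocount does not explain this move, and its cause was not tested. Of the 21 lists called by camera, 17 passed under each of 18 alternatives besides the estimated correlation, which ended 18 calls. The luminal list failed 11 of the 18 (adjusted p 0.0102 to 0.113 over all 18), the iron list 6 (0.0006 to 0.203), the metallothionein list 6 (3.05e-09 to 0.155) and the heat shock list 3 (0.00684 to 0.203). The iron and metallothionein lists failed with limma and quantile normalisation, and the cause was not tested. The setting with an estimated correlation also ended the call of the iron list, whose estimate of -0.0143 lay under the preset 0.01. The p53 list, estimated at 0.0093, went from an adjusted p of 4.78e-13 to 0.0156 with camera. In the simulated counts, whose genes were independent, the raised list likewise went from a camera p of 4.87e-46 to 9.58e-05. The lost calls therefore do not show that list members were correlated. The basal list, not called by the edgeR fit, passed under 7 of 18 (adjusted p 0.0371 to 0.108), and the respiratory chain list under quantile normalisation (0.0163). Camera's direction for the growth factor receptor list, which was never called, turned to lower under quantile normalisation (median -0.35, adjusted p = 0.587) and under limma with log2(CPM + 0.5) (median -0.307, also without a trend or with a robust fit), log2(CPM + 0.1) (-0.31) and log2(CPM + 1) (-0.304), and its cause was not tested. The direction for the endothelial list, also never called, turned without Control replicate 1 (median 0.65, adjusted p = 0.998), while its median ranged from 0.592 to 0.736 with 1 library left out. The median of the fibroblast list changed sign without a filter, to 0.048 (adjusted p = 0.603). No call was made at the 0.5 CPM minimum for 13879 genes, part of which were tested without a filter, and how far depth limits them was not tested. For genes with 0 reads in a group, depth limits the fold to a bound.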

Other observations

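The gene families of the next paragraphs were chosen after their values were seen, as were the values per host gene, per class and for host exons given for small RNAs, the comparison of numbers of shared words between metallothioneins and that of gene lists in Control replicate 1; the other tests were set before their results were seen. All camera p-values over the 7 families are descriptive only, since the families were picked on the same values. Genes of the collagen prolyl and lysyl hydroxylases, enzymes that modify collagen, rose in 7 of 7 tested members. Their median log2 fold change was 1.88 (camera adjusted p = 6.4e-12 over 7 families, and 0.0201 with an estimated correlation). P4HA2 rose by 4.16, P4HA1 by 3.80 and PLOD1 by 2.63 on the log2 scale, and P4HA1 and P4HA2 are also on the list of HIF targets. The catalytic subunits need iron, whereas P4HB, which rose by 1.45, encodes protein disulfide isomerase, the non-catalytic subunit of the prolyl hydroxylases. HIF1A, which encodes the HIF-1 alpha subunit, fell by 0.97. Of 17 HOX genes, which set positional identity in development, 11 were higher, 3 lower and 3 not called, with a median of 1.18 (camera adjusted p = 0.0107), and an adjusted p of 0.0884 with an estimated correlation. HOXA13 rose from 1.44 ± 0.050 to 63.5 ± 4.76 CPM (SD, n = 3). Most of the HOX genes lay under 2 CPM in controls, and HOXD10, from 0.034 to 1.30 CPM, passed the minimum for testing through the DpC libraries. HOXC13 and HOXC11, the HOX genes highest in controls, fell from 16.4 to 11.2 and from 6.71 to 4.09 CPM. Of 54 rows of protocadherins, cell adhesion genes mostly in clusters of close paralogs, 7 were higher, 38 lower and 9 not called. The rows include the pseudogenes PCDHB18P and PCDHB19P. The median was -0.77 (camera adjusted p = 0.0147), with an adjusted p of 0.0884 with an estimated correlation.

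Cytosolic and mitochondrial ribosomal protein genes had medians of opposite sign, a difference that was not itself tested. Of 82 cytosolic genes 74 were higher, 5 lower and 3 not called, with a median of 0.37 (camera adjusted p = 0.00285), and an adjusted p of 0.301 with an estimated correlation, but with library totals the median was 0.11, with 37 higher and 7 lower. Of 76 mitochondrial genes 12 were higher, 46 lower and 18 not called, with a median of -0.32 and -0.58 with library totals (camera adjusted p = 0.0124), and an adjusted p of 0.268 with an estimated correlation. Small nucleolar RNAs (snoRNAs), which guide modification of ribosomal RNA, were not called as a family (7 higher, 43 lower and 17 not called of 67, median -0.788, camera adjusted p = 0.0662). The glucose transporter rows SLC2A14 and SLC2A3, which are close paralogs and can share reads, rose by 6.86 and 6.02 on the log2 scale. The chemokine CXCL8 rose by 4.37, and the stem cell factor SOX2 fell by 4.09. PGK2, a retrogene of the glycolysis gene PGK1, held 57 reads in controls and 0 after DpC, at least 13.4-fold lower, but lay under the minimum for testing, so no call was made, while PGK1 rose by 3.44.

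Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many calls, the real one, with 11417 genes and 4045 at least 2-fold changes against 0 and 0 for the highest other split. A set of 10 splits cannot give a share under 0.05. Each other split also put both treatments into each group, so the difference between treatments counted as spread and few calls could arise. The contrast therefore does not bear on chance.

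Of the metallothionein genes without a read in any control, 4 held 80 reads or more after DpC: MT4, MT1DP, MT1B and MT1G, of which MT1G lay under the minimum for testing. The GENCODE transcripts of MT4, MT1DP and MT1B shared no 31-base words with the abundant paralogs MT1F, MT1X and MT2A. Within these transcripts, reads of stretches identical over 31 bases are argued against. The transcripts were short, with 240, 120 and 392 words against 1904 for MT1F. The annotation of the counted rows is not given, and RefSeq places MT1DP at 56643687 to 56644941 against 56643725 to 56644765 in GENCODE. Shared stretches outside the GENCODE transcripts therefore stay open. Reads of MT1F, MT1X and MT2A placed with mismatches were not tested and also stay open. By the share of a row's own words, 4 of 4 rows had a metallothionein row with an equal or higher share and under 10% of the reads. MT1G shared 11.2%, and MT1A, with 2 reads, 12.6%. By the number of words 3 of 4 did, since MT1G shared 90 words and MT1A 46, so shared reads stay open for MT1G. With no shared words, MT4, MT1DP and MT1B met either condition against any row almost without reads, so these counts add nothing for them. Transcription running on from an upstream gene on the same strand is argued against, since 0 of 4 rows had such a neighbour within 10 kb with at least as many reads. Run-on from the opposite strand was not tested. It stays open for MT1G, which lies on the other strand from MT1F (191459 reads after DpC), since counting by strand is not stated. A response of MT4, MT1DP and MT1B to DpC, which the design allows, may explain their reads and remains a hypothesis found on the same data.

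Long non-coding RNA genes had a median log2 fold change of -0.579 over 845 genes, with 183 higher, 464 lower and 198 not called (camera adjusted p = 0.0158 over 7 families), and an adjusted p of 0.11 with an estimated correlation, against a median of -0.033 over 13171 protein-coding genes. Low expression is argued against as the whole cause, since 10000 draws of protein-coding genes matched on expression, which treat genes as independent, gave medians no lower than -0.243. Reads of overlapping genes are argued against in the same way for genes in the RefSeq table. The 207 lncRNA genes that overlap no other gene there had a median of -0.785, below the lowest matched median of -0.402. A smaller share of unspliced RNA in the DpC libraries stays open: 81 small RNA rows inside 51 host genes lay below their host by a median log2 difference of -1.14, 64 of them below 0 (exact sign test, p = 1.43e-07), and by -0.758 with 1 value per host, in 34 of 51 hosts (p = 0.0241), but such a change should lower both classes, and 55 of 60 snoRNA rows lay below (median over hosts -1.33) against 9 of 21 miRNA rows (median over hosts 0.259), a difference of -1.59 (two-sided permutation test over hosts, p = 4e-05). Moreover, 53 snoRNA and 14 miRNA rows overlap an annotated exon of their host, so the rows do not measure introns alone and this test does not decide. Hosts were matched by position without comparing strand, so some rows may lie antisense to the gene named as host. Of the rows that overlap no host exon, 4 of 7 snoRNA rows lay below (median over hosts -0.492, 95% interval -1.88 to 0.309). For miRNAs 3 of 7 such rows did (median over hosts 0.226, 95% interval -1.39 to 0.855), so these rows do not decide either. Neither a change in snoRNAs themselves nor lower transcription of lncRNA genes after DpC was tested.

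Control replicate 1 stood apart from the other controls. Its deviation from them correlated with GC content at a Spearman rho of -0.724 across 14157 genes, which are not independent replicates, and with transcript length at 0.135. Control replicate 2 minus replicate 3 correlated with GC content at -0.105. The log2 fold changes of DpC against control correlated with GC content at 0.193, and what part of this came from Control replicate 1 was not tested. Deeper sequencing is argued against, since after thinning to 31393343 reads each the chi-square per degree of freedom between Control replicates 1 and 2 was 7.39 times that between replicates 2 and 3. A GC-dependent difference in library preparation may explain part of the deviation but is argued against for the interferon-stimulated list. The list's median deviation of 0.226 lay above each of 10000 medians of genes matched on GC content and expression (highest 0.0975). The draws treat genes as independent, and the GC-rich members IRF7 and ISG15 deviated by -1.02 and -0.772. Of 28 lists, mitosis also lay above and the replication-dependent histones below each of their matched medians. In all, 6 lists lay above and 3 below the central 95% of their matched medians. The draws may therefore be too narrow for gene lists, which weakens the argument. Control replicates 2 and 3 differed in interferon-stimulated genes too, by a median of -0.228, so a difference between cultures in these genes stays open, though the labels name no separate cultures, and no biological explanation was tested. HSPB1 lay 1.17 below the other controls on the log2 scale, and its log2 fold change was 1.71 with Control replicate 1 and 1.46 without it.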
